A study of Mus musculus with 9 samples.

How the data were processed

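RNA was measured in the dorsal lateral geniculate nucleus (dLGN), the thalamic relay between the retina and the visual cortex, of C57BL/6J mice. Per the labels, the mice were kept in darkness from postnatal day 20 to postnatal day 27, and were then exposed to light for 0, 1 or 8 h before the tissue was dissected from brain slices and frozen. Each light time has 3 libraries, numbered 1 to 3, and the labels count 3 mice per light time as independent samples. Mice of both sexes were used, and the sex behind each library is not given in the sources used here. Libraries were made from total RNA after removal of ribosomal RNA and were sequenced on a NextSeq 500 instrument, per the labels' protocols.

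The deposited data are 4 tables, with genes of higher and of lower expression for 1 h against 0 h and for 8 h against 0 h. The gene values used here are the deposited raw counts per gene and library, which are whole numbers. Per the submitters' processing notes, BWA, edgeR 3.14.0 and the mouse genome build GRCm38 (mm10) were used, without a statement of which step each served. The counting program, the annotation release and the strand setting are not given in the sources used here. The tables also hold a density per library, a signal the authors made by dividing the count by the exonic length and by a constant for each library. The density was only checked against the counts. The authors' deposited tables further give a fold change (ratio of light over 0 h), a p-value and an FDR per gene, which are quoted here only as theirs.

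The tables for 1 h hold 20011 genes and those for 8 h hold 20399, of which 19703 are in both. Every gene had at least 4 reads over the 6 libraries of its comparison, so genes below that level were not analysed here. The counts of the 0 h libraries were identical in both sets of tables. There were 25 deposited gene symbols stored as dates, and all 25 were restored through their Entrez gene number. Gene positions are those of the deposited tables, counted from 1 on GRCm38. Of 19319 genes that could be compared with a GRCm38 reference annotation, 99.9% overlapped the reference gene of the same number.

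Total counts ran from 5.73 M (0 h replicate 1) to 22.6 M (8 h replicate 1). With 3 reads as the floor of detection, a gene becomes visible at 0.524 CPM (counts scaled to library size) in the shallowest library and at 0.133 CPM in the deepest. These floors cover counting error only. Each library was counted as its own replicate, since the labels give independent samples. Replicates of a group differed by a chi-square per gene between 4.92 and 22.6 over counting noise, which does not show that they came from separate mice.

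Differential expression was tested with the quasi-likelihood method of edgeR 4.0.16 (glmQLFit and glmQLFTest with the package defaults) in R 4.3.3. TMM scaling and the filterByExpr filter were used, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons of 1 h with 0 h and of 8 h with 0 h were each fitted on their own 6 libraries, with 15164 and 15330 genes tested. The difference between 8 h and 1 h was tested in a fit of all 9 libraries over 15586 genes. Standard errors (SE) of log2 fold changes were derived from the fold change and the F statistic. Expression levels are given as CPM with TMM-scaled library sizes of all 9 libraries, as mean ± SD. All tests were two-sided. The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. An option of glmQLFit (legacy) was not fixed: results with both of its values had been seen when the package default was taken, and the other value is reported as an alternative.

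In total 32 gene lists were tested with camera (limma 3.58.1) on voom values. They covered activity responses, signalling pathways, channels and receptors, cell types of the dissected area and its neighbours, and signs of the make-up of the RNA. The preset correlation between genes was 0.01, and p-values were adjusted over the lists and both comparisons with 0 h, 64 tests together. The same lists were tested between 8 h and 1 h as a contrast added later, adjusted over its 32 tests. Every list was tested again with an estimated correlation per list and with fry, a rotation test of whether the genes of a list move on balance in a single direction. With an estimated correlation, camera also takes its residual degrees of freedom from the libraries and not from the number of genes. These were 4 in the comparisons with 0 h and 6 between 8 h and 1 h. A call lost in that setting is therefore not shown to be due to correlation between genes, nor to the degrees of freedom alone. For lists called against 0 h, the estimates ran from -0.015 (rapid activity, 8 h) to 0.897 (mitochondrially encoded genes, 8 h). At 1 h they were 0.333 for the rapid activity list and 0.802 for blood genes. Where the estimate lies above the preset 0.01, the p-value with the preset may be far too small. Lists share members: Mertk and Nfkbia, for instance, are in the glucocorticoid-induced list and in others.

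The genes named in the text follow a fixed rule. For each comparison it takes Tnfrsf12a and Tnfsf12. It adds the 12 largest rises and the 8 largest falls among called genes whose groups do not overlap and whose mean is at least 1 CPM, without predicted or non-coding transcripts of unknown function. For each list it adds up to 4 called members by smallest adjusted p, or up to 2 members by smallest p where none was called. Genes named outside this rule are marked as chosen after their values were seen.

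The procedure was tested on simulated counts with known changes. Of the genes changed 2-fold in simulated data, 84.8% were called among 14996 genes in the design of 1 h and 79.1% among 15189 genes in that of 8 h. For a 1.5-fold change these shares were 47.7% and 70.1%. False calls made up 5.1% and 7.0% of all calls. Each design was simulated as a single data set with many changed genes. In that of 1 h, 65, 66 and 64 tested genes were changed 1.5-, 2- and 4-fold. Many true changes ease the adjusted threshold, so these shares do not give the power where few genes are called, as at 1 h. A gene not called there is not shown to be unchanged.

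Alternatives were other scalings (RLE factors, library totals only), other filters, other tests (DESeq2 1.42.0, limma-voom, the exact test of edgeR), other sets of libraries, a block for the replicate number, a covariate for Xist, a threshold of 1.5-fold, and leaving out each library in turn. After the data were seen, 3 more were added, namely fits without the libraries that hold cortical and hippocampal transcripts, a covariate for those transcripts, and the other option of glmQLFit. Summaries and figures were made with Python 3.11.15, pandas and matplotlib.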

Results

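Sequencing of total RNA gave counts for 9 dLGN libraries, 3 after 0 h, 3 after 1 h and 3 after 8 h of light. The 0 h mice had spent a week in darkness and served as the baseline. Total gene counts averaged 13.1 M ± 6.60 (SD, n = 3) at 0 h, 14.5 M ± 4.94 (SD, n = 3) at 1 h and 19.6 M ± 2.66 (SD, n = 3) at 8 h. In the order of the replicates, they were 5.73, 18.4 and 15.2 M at 0 h, 8.77, 17.0 and 17.7 M at 1 h, and 22.6, 18.9 and 17.4 M at 8 h. According to its title, the series asks how visual experience controls Fn14, the receptor encoded by Tnfrsf12a, in the maturation of connections from the retina to the thalamus. The comparisons with 0 h therefore ask which genes the return of light changes, early and late.

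Some measured properties of the libraries bear on every comparison. Xist, the RNA that coats the inactive X chromosome of females, and Y-linked RNA were both present in 7 of the 9 libraries. In 0 h replicate 3, Xist stood at 0.334 CPM and the Y-linked gene Ddx3y at 60.6 CPM, and in 8 h replicate 2 they stood at 852 and 0.053 CPM. Neurod6, a transcription factor of cortical and hippocampal excitatory neurons, reached 18.3 CPM in 0 h replicate 2 and 13.9 CPM in 1 h replicate 1. It was at 3.62 CPM in 8 h replicate 1 and at no more than 0.735 CPM in the other 6 libraries. Gad2, an enzyme of GABA synthesis, was lowest in 0 h replicate 2, at 55.1 CPM, with a range up to 173 CPM. Xist, Ddx3y, Neurod6 and Gad2 were chosen here after their values were seen.

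**Figure D1:**
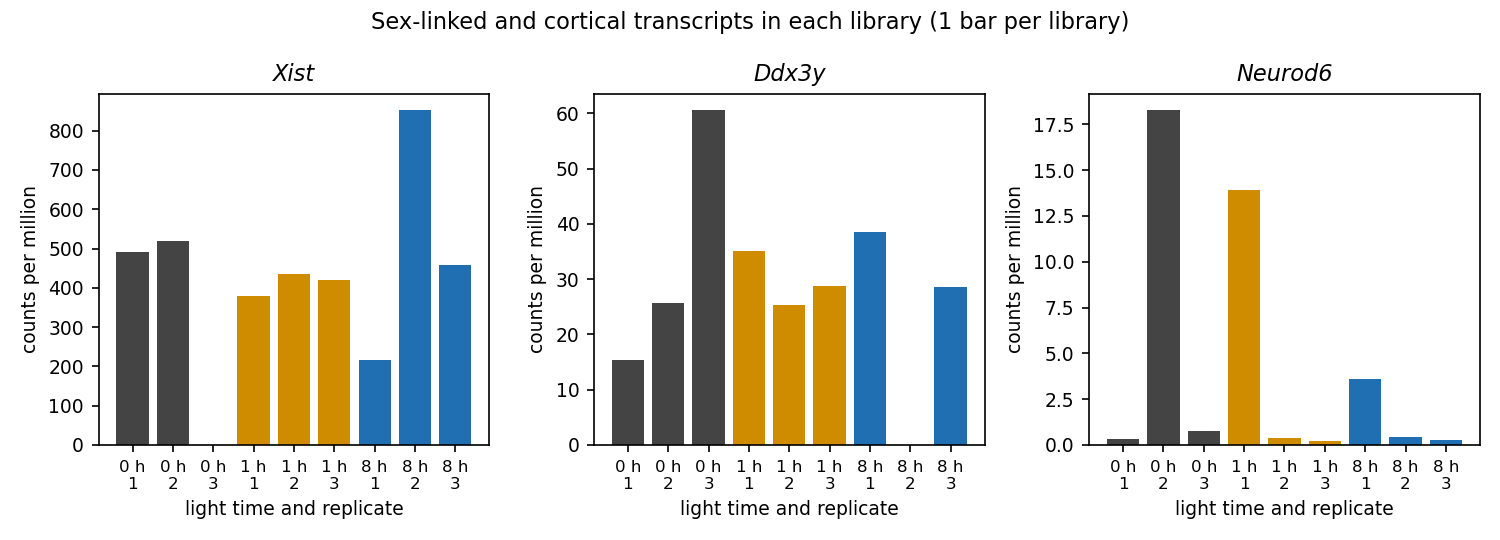
Scaled counts in CPM (vertical axes) of Xist, Ddx3y and Neurod6 in each of the 9 libraries, with 1 bar per library labelled by light time and replicate number. Xist is at 0.334 CPM in 0 h replicate 3, Ddx3y is at 0.053 CPM in 8 h replicate 2, and Neurod6 is highest in 0 h replicate 2, at 18.3 CPM.

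After 1 h of light, Fosb and Fosl2, which encode AP-1 transcription factors made within minutes to hours of neuronal activity, were the 2 genes that passed the test. Fosb rose from 0.674 CPM ± 0.181 to 8.06 CPM ± 3.53 (SD, n = 3 each), a log2 fold change of 3.49 ± 0.41 (SE, adjusted p = 0.0427). Fosl2 rose from 5.99 CPM ± 0.217 to 14.3 CPM ± 1.22 (SD, n = 3 each), a log2 fold change of 1.24 ± 0.13 (SE, adjusted p = 0.0224). Both genes were higher in each of the 3 libraries at 1 h than in any of the 3 at 0 h. Over all tested genes the groups of 8.6% did not overlap at 1 h, where chance gives 10%. Fosb (Entrez gene 14282) lies on the minus strand of chromosome 7 at positions 19302696 to 19310232, and Fosl2 (Entrez gene 14284) on the plus strand of chromosome 5 at 32136472 to 32157840. Each has 4 annotated exons.

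No gene fell at 1 h in the edgeR test, and DESeq2, limma-voom and the exact test called none lower either. At an unadjusted p under 0.05, 288 genes were higher and 198 lower of 15164 tested. DESeq2 called 14 genes and the exact test 17, all higher. In 20 simulated data sets without any change, the edgeR test called 1.8 genes on average at 1 h and 1.6 at 8 h. The count of 2 at 1 h is near that mean, whose spread is not given. The mean speaks to the count alone, and cannot decide whether Fosb and Fosl2 in particular are false calls. The authors' deposited table lists 15 genes higher and 0 lower at an FDR under 0.05, and both genes called here are among them. The calls of Fosb and Fosl2 were lost in several alternatives. With all 6 libraries, the count was 0 with a block for the replicate number and 0 with Xist as a covariate. Leaving out 0 h replicate 1, 2 or 3 or 1 h replicate 1 or 2 gave 0 calls, and leaving out 1 h replicate 3 gave 9, both genes included. The count was also 0 without the 2 libraries with the most Neurod6.

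Of 33 measured genes of the rapid activity response, 2 rose and 31 did not pass over all genes, while 17 rose adjusted over the list alone. The list was higher as a group (camera, adjusted p = 8.49e-24), with a median log2 fold change of 0.54 and 30 members above 0. With an estimated correlation between genes, which was 0.333, this call was lost (adjusted p = 0.366). Members that did not pass over all genes included the early genes Fos, at a log2 fold change of 2.01 ± 0.37 (SE), Npas4, at 1.82 ± 0.30 (SE), Egr1, at 1.62 ± 0.27 (SE), and Nr4a1, at 1.21 ± 0.19 (SE). These 4 were chosen after their values were seen.

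Negative feedback regulators of ERK signalling were also higher as a group at 1 h (camera, adjusted p = 5.56e-08, and adjusted p = 0.275 with an estimated correlation). None of the 16 measured members passed over all genes, and 5 rose adjusted over the list alone. Dusp1, a phosphatase that inactivates MAP kinases, stood at 34.4 CPM ± 4.62 at 0 h and 71.6 CPM ± 19.6 at 1 h (SD, n = 3 each), a log2 fold change of 1.06 ± 0.19 (SE, adjusted p = 0.259). Dusp4, a related phosphatase, had a log2 fold change of 0.83 ± 0.14 (SE, adjusted p = 0.225). Dusp1 is also in the rapid activity list. Among the delayed activity genes, none of 36 passed over all genes and 1 rose adjusted over the list alone. Its member Trib1, a pseudokinase, had a log2 fold change of 0.92 ± 0.13 (SE, adjusted p = 0.165), and Igf1, a growth factor, 0.59 ± 0.18 (SE, adjusted p = 1.00). This list was called higher (adjusted p = 0.00331, and adjusted p = 0.374 with an estimated correlation), but not without 1 h replicate 1 (adjusted p = 0.0536).

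In the circadian list, the period genes Per1 and Per2 had log2 fold changes at 1 h of 0.53 ± 0.13 (SE) and 0.56 ± 0.15 (SE), and both rose adjusted over the list alone, while none of 22 members passed over all genes. The list was called higher (adjusted p = 0.00349, and adjusted p = 0.374 with an estimated correlation), but not without 0 h replicate 3 (adjusted p = 0.129) or 1 h replicate 2 (adjusted p = 0.140). Heat shock and ER stress genes were higher as a group (adjusted p = 2.21e-08, and adjusted p = 0.374 with an estimated correlation), with the co-chaperone genes Dnajb1 at 0.30 ± 0.08 and Dnajb5 at 0.30 ± 0.08 (log2 ± SE), and none of 27 members passed over all genes or adjusted over the list alone.

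Nuclear non-coding RNAs, a sign of the nuclear share of the RNA, were higher (adjusted p = 0.000701, and adjusted p = 0.374 with an estimated correlation). Ribosomal protein genes were lower (adjusted p = 0.0146, and adjusted p = 0.374 with an estimated correlation). The ribosomal list was not called without 0 h replicate 3 (adjusted p = 0.369) or 1 h replicate 1 (adjusted p = 0.0966). Blood genes were higher, with a median of 0.39 over 6 measured members (adjusted p = 1.26e-05, and adjusted p = 0.374 with an estimated correlation). The glucocorticoid-induced list was not called at 1 h (adjusted p = 0.558, and adjusted p = 0.0358 without 0 h replicate 3).

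Markers of myelinating oligodendrocytes were lower as a group at 1 h, with a median log2 fold change of -0.12 and 16 of 18 members below 0 (camera, adjusted p = 6.13e-07, and adjusted p = 0.374 with an estimated correlation). Mal and Cnp, which encode myelin proteins, stood at -0.22 ± 0.06 and -0.23 ± 0.08 (log2 ± SE). Microglia markers were lower as well, with a median of -0.08 (adjusted p = 0.00159, and adjusted p = 0.374 with an estimated correlation). Their member P2ry13, a purine receptor, stood at -0.48 ± 0.17 (log2 ± SE). Cnp and P2ry13 overlap Dnajc7 and Med12l on the other strand. No member of these lists passed over all genes or adjusted over the list alone. In total 12 of 32 lists were called at 1 h, 9 higher and 3 lower, of which 7 were called without each library in turn, and 0 were called with an estimated correlation or with fry.

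At 1 h Tnfrsf12a itself stood at 8.12 CPM ± 0.917 against 5.38 CPM ± 1.08 at 0 h (SD, n = 3 each). Its log2 fold change of 0.55 ± 0.17 (SE) had an unadjusted p of 0.0101 and did not pass over all genes (adjusted p = 1.00). Tnfsf12, which encodes TWEAK, the ligand of Fn14, had a log2 fold change of 0.34 ± 0.24 (SE, adjusted p = 1.00). Among the other genes of the Fn14, TNF receptor and NF-kB list, Nfkbiz had 0.52 ± 0.17 (SE, adjusted p = 1.00). None of 27 measured members of that list passed over all genes or adjusted over the list alone.

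**Figure D2:**
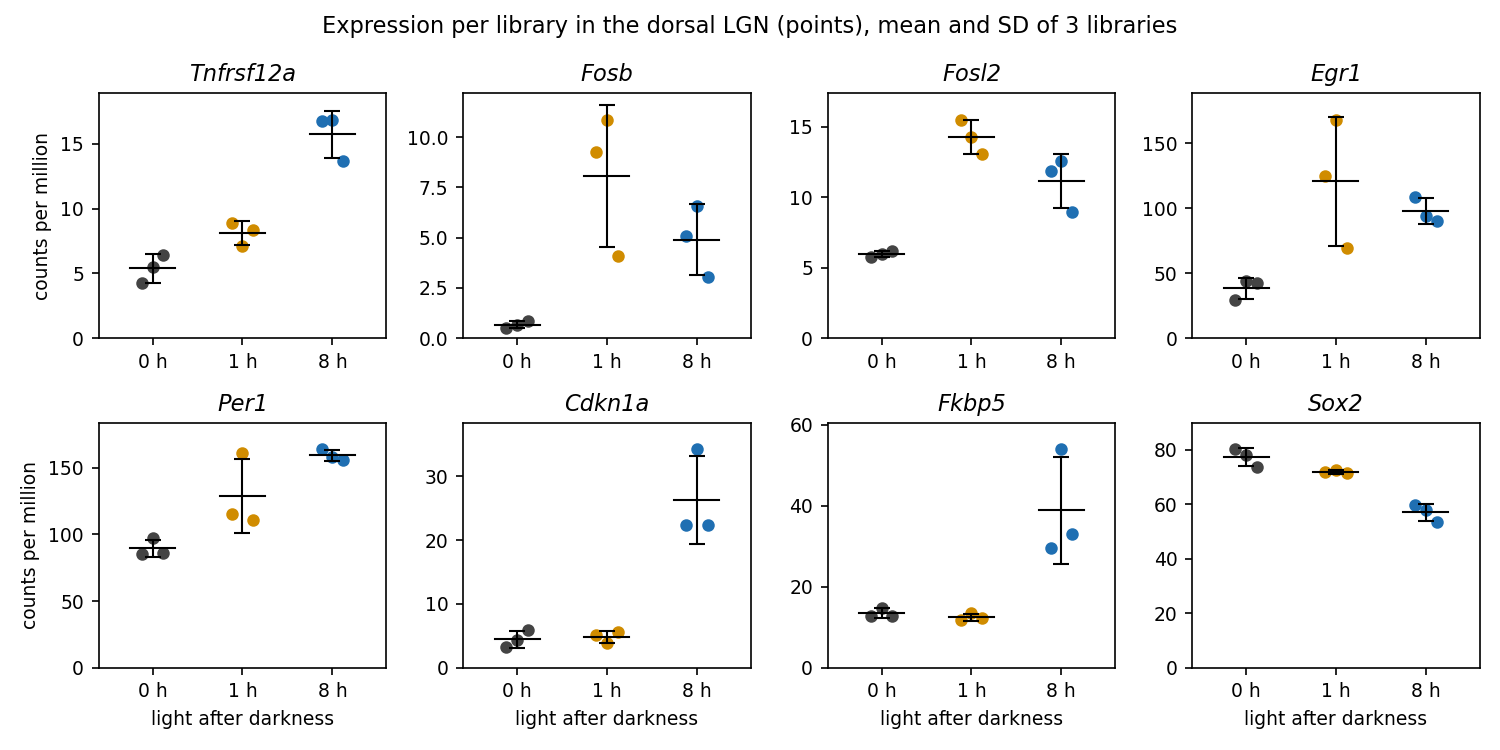
Scaled counts in CPM (vertical axes) after 0, 1 and 8 h of light (horizontal axes) for 8 genes. Points are libraries, long lines are means and error bars are SDs of 3 libraries. Tnfrsf12a averages 5.38, 8.12 and 15.7 CPM at the 3 times, Fosb 0.674, 8.06 and 4.89 CPM, and Cdkn1a 4.50, 4.84 and 26.3 CPM.

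After 8 h of light, Tnfrsf12a had risen, together with 12 of 24 glucocorticoid-induced genes and 8 of 32 genes of the rapid activity response. Tnfrsf12a reached 15.7 CPM ± 1.81 against 5.38 CPM ± 1.08 at 0 h (SD, n = 3 each), a log2 fold change of 1.51 ± 0.15 (SE, adjusted p = 0.00179), or 2.84-fold. Larger rises were seen for Plin4, which coats lipid droplets, at 3.18 ± 0.37 (log2 ± SE, adjusted p = 0.00396), and for Cdkn1a, the cell cycle inhibitor p21, at 2.48 ± 0.22 (adjusted p = 0.0011). Hif3a, a member of the family of hypoxia-inducible factors, rose by 2.30 ± 0.14 (adjusted p = 0.000155). Fosb was still higher than at 0 h, by 2.79 ± 0.35 (adjusted p = 0.0064).

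In total 90 of 15330 genes were called at 8 h, 81 higher and 9 lower, by the quasi-likelihood test of edgeR. The rises had a median log2 fold change of 0.65 and the falls of -0.54. All 90 genes are among the 238 with an FDR under 0.05 in the authors' deposited table (197 higher, 41 lower), which gives Tnfrsf12a a fold change of 2.86. DESeq2 called 270 genes and the exact test 269. Fits without 0 h replicate 1, 8 h replicate 2, 8 h replicate 3 or 8 h replicate 1 called 49, 33, 60 and 65 genes, of which 42, 32, 55 and 53 were among the 90. The groups of 16.3% of tested genes did not overlap, where chance gives 10% for 3 libraries against 3. Those of all 90 called genes did not overlap, which passing the test favours and which adds no separate support.

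Tnfrsf12a (Entrez gene 27279) lies on the minus strand of chromosome 17 at 23675445 to 23677449 and has 4 annotated exons. Its last 80 bases overlap Hcfc1r1 on the other strand, and the strand setting of the counts is not given in the sources used here. Hcfc1r1, named here for that overlap, had a log2 fold change of 0.12 (adjusted p = 0.851). Tnfrsf12a was called at 8 h in every alternative run for it, with log2 fold changes between 1.42 and 1.64 when single libraries were left out. Tnfsf12 had a log2 fold change of 0.25 ± 0.21 (SE, adjusted p = 0.759). It shares 9859 bases on its own strand with an annotated readthrough transcript, so its count is uncertain. In the Fn14, TNF receptor and NF-kB list, 2 of 27 measured genes rose, Tnfrsf12a and Nfkbia, an inhibitor of NF-kB, at 1.06 ± 0.12 (log2 ± SE, adjusted p = 0.00287). The same 2 rose adjusted over the list alone, and the list was not called (camera, adjusted p = 0.178).

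Of 24 measured glucocorticoid-induced genes, 12 rose and 12 did not pass, while 19 rose adjusted over the list alone. The median log2 fold change was 0.96 and 23 members were above 0. The list was higher as a group (camera, adjusted p = 2.39e-27; fry, adjusted p = 0.0223), and this call was lost with an estimated correlation (adjusted p = 0.117). It was called without each library in turn, with adjusted p between 4.02e-31 and 3.70e-22. Besides Cdkn1a and Plin4, the members that rose included Zbtb16, a zinc finger repressor, from 20.8 CPM ± 2.89 to 78.2 CPM ± 19.9 (SD, n = 3 each), a log2 fold change of 1.94 ± 0.18 (SE, adjusted p = 0.0011). Sgk1, a kinase that regulates ion channels, rose by 1.08 ± 0.10 (SE, adjusted p = 0.00118), and Fkbp5, a co-chaperone of the glucocorticoid receptor, by 1.52 ± 0.21 (SE, adjusted p = 0.0106). Map3k6, a stress-activated kinase, rose by 1.86 ± 0.20 (SE, adjusted p = 0.0028). Mertk, a receptor for the engulfment of cellular debris, rose by 0.87 ± 0.08 (SE, adjusted p = 0.00128).

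Of 32 measured genes of the rapid activity response, 8 rose at 8 h and 24 did not pass. Adjusted over the list alone, 14 rose and 2 fell. The list was higher as a group (camera, adjusted p = 2.95e-10, and fry, adjusted p = 0.00429). This call was lost in the setting with an estimated correlation (adjusted p = 0.0960), although the estimate, -0.015, was below the preset 0.01. Egr1, an early transcription factor, rose from 38.5 CPM ± 7.93 to 97.7 CPM ± 9.81 (SD, n = 3 each), a log2 fold change of 1.32 ± 0.13 (SE, adjusted p = 0.00127). Per1 rose by 0.83 ± 0.07 (SE, adjusted p = 0.000567) and Dusp1 by 0.85 ± 0.11 (SE, adjusted p = 0.00696). Per1 and Per2 were the 2 members of the circadian list of 22 that rose, and 3 rose adjusted over the list alone, Per2 by 0.93 ± 0.15 (SE, adjusted p = 0.0218). That list was called higher (adjusted p = 0.00225, and adjusted p = 0.374 with an estimated correlation). Of 16 ERK feedback genes, Dusp1 was the 1 that rose, with 4 adjusted over the list alone, and the list was called higher (adjusted p = 0.0188, and adjusted p = 0.554 with an estimated correlation) but not without 8 h replicate 1 (adjusted p = 0.0638) or 2 (adjusted p = 0.0751).

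Among delayed activity genes, 2 of 36 rose over all genes and adjusted over the list alone. These were Trib1, by 1.09 ± 0.09 (log2 ± SE, adjusted p = 0.000567), and Vgf, which encodes a secreted neuropeptide precursor, by 0.59 ± 0.08 (SE, adjusted p = 0.00797). The list was called (adjusted p = 0.0242, and adjusted p = 0.554 with an estimated correlation), but not without 0 h replicate 1 (adjusted p = 0.116) or 8 h replicate 2 (adjusted p = 0.0888). Of 33 potassium and HCN channel genes, 1 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone. Kcnn3, a calcium-activated channel, rose by 0.52 ± 0.09 (SE, adjusted p = 0.0341), and the expression of Kcnq5, which carries the M current, fell by 0.94 on the log2 scale (adjusted p = 0.0344). Both calls depend on the libraries: of the 6 fits without a single library, 1 called Kcnn3 (without 8 h replicate 3) and 1 called Kcnq5 (without 0 h replicate 3). Over all alternatives the adjusted p ran up to 0.188 for Kcnn3, which was also not called with the Xist covariate (0.102), and up to 0.310 for Kcnq5. The channel list was called higher (adjusted p = 0.00159, and adjusted p = 0.374 with an estimated correlation).

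Other rises by size included Tekt4, at 2.50 ± 0.38 (log2 ± SE, adjusted p = 0.0165), Cftr, a chloride channel, at 1.73 ± 0.21 (adjusted p = 0.0045), Car7, a carbonic anhydrase of neurons, at 1.62 ± 0.15 (adjusted p = 0.0011), and Ppp1r3g, a regulator of glycogen synthesis, at 1.58 ± 0.22 (adjusted p = 0.012). Tekt4 averaged 0.519 CPM at 0 h and overlaps Cacna1h on the other strand by 139 bases. The falls were smaller. Tnc, an extracellular matrix protein, went from 104 CPM ± 9.86 to 64.9 CPM ± 11.3 (SD, n = 3 each), a log2 fold change of -0.68 ± 0.11 (SE, adjusted p = 0.0282). Mmp14, a membrane-bound matrix protease, changed by -0.65 ± 0.12 (SE, adjusted p = 0.0398), and Sox2, a transcription factor of glia and neural progenitors, by -0.43 ± 0.07 (SE, adjusted p = 0.0245). Sox2 lies within the longer transcript Sox2ot on the same strand. Trim59, Fam101b and Zfp804a also fell, with log2 fold changes of -0.54, -0.54 and -0.40. None of these falls held throughout: Tnc, Trim59 and Zfp804a were called in 2 of the 6 fits without a single library, and Mmp14, Sox2 and Fam101b in 1. Of 33 named genes called at 8 h, 18 were called in all 6 of these fits. Tekt4 was called in 3, Fkbp5 in 4, Per2 in 2 and Ppp1r3g in 5.

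Sterol synthesis genes were lower as a group at 8 h, with 21 of 25 members below 0 and a median of -0.17 (camera, adjusted p = 1.33e-06, and adjusted p = 0.498 with an estimated correlation). None passed over all genes or adjusted over the list alone. Hmgcs1, an enzyme of the mevalonate pathway, stood at -0.33 ± 0.09 (log2 ± SE, adjusted p = 0.168). Interferon-stimulated genes were lower as a group, with a median of -0.30 (adjusted p = 0.00159, and adjusted p = 0.554 with an estimated correlation). Gbp2, a guanylate-binding protein of that list, stood at -1.04 ± 0.29 (SE, adjusted p = 0.180), at 2.06 CPM ± 0.655 and 1.05 CPM ± 0.114 (SD, n = 3 each) at 0 and 8 h. Oligodendrocyte markers (median -0.11, adjusted p = 0.00109) and microglia markers (median -0.15, adjusted p = 0.00331) were again lower. With an estimated correlation their adjusted p was 0.554 and 0.374. Adjusted over the list alone, 1 oligodendrocyte marker and 2 microglia markers fell. Opalin, a myelin protein, stood at -0.42 ± 0.10 (SE, adjusted p = 0.124), and Cx3cr1, a chemokine receptor of microglia, at -0.31 ± 0.07 (SE, adjusted p = 0.124). Nuclear non-coding RNAs were again higher, with 9 of 11 above 0 (adjusted p = 0.0377, and adjusted p = 0.374 with an estimated correlation). They were not called without 0 h replicates 1 or 3 or 8 h replicates 2 or 3 (adjusted p = 0.0797, 0.196, 0.0886 and 0.113). In total 14 of 32 lists were called at 8 h, 10 higher and 4 lower, of which 8 were called without each library in turn, 2 with fry and 0 with an estimated correlation.

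**Figure D3:**
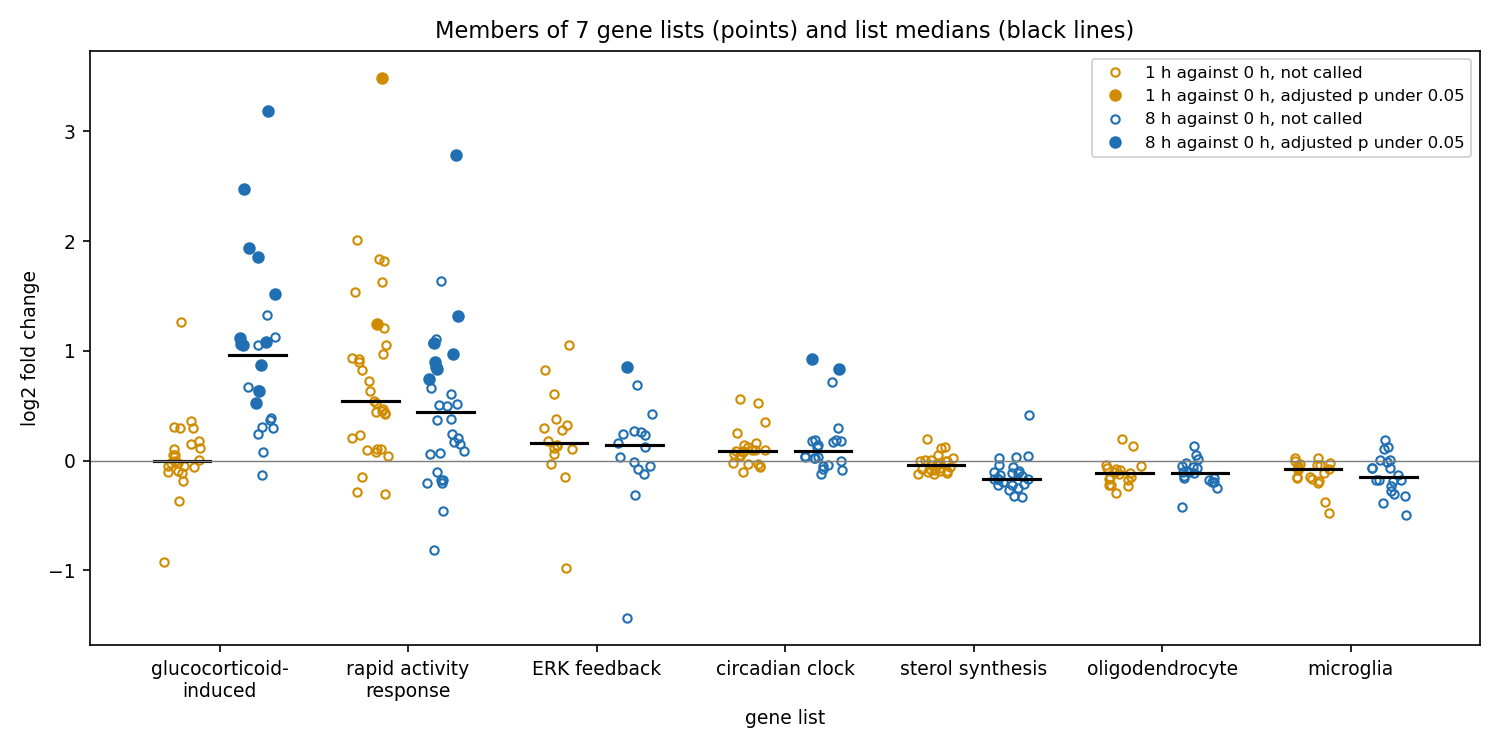
Log2 fold changes (vertical axis) of the measured members of 7 gene lists (horizontal axis) at 1 h and at 8 h against 0 h. Each point is a gene, filled where its adjusted p is under 0.05, and black lines are list medians. The glucocorticoid-induced list has a median of 0.00 at 1 h and 0.96 at 8 h, and the rapid activity list 0.54 and 0.44.

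The direct comparison of 8 h with 1 h asks which genes differ between the late and the early response. Glucocorticoid-induced genes were among the largest rises, with Plin4 by 4.12 ± 0.37 (log2 ± SE, adjusted p = 0.000434), Cdkn1a by 2.45 ± 0.22 (adjusted p = 0.000434) and Zbtb16 by 1.92 ± 0.19 (adjusted p = 0.000568). Tnfrsf12a was also higher at 8 h than at 1 h, by 0.97 ± 0.14 (adjusted p = 0.0131). Npas4, an activity-induced transcription factor of neurons, was lower at 8 h, at 14.2 CPM ± 2.41 against 35.6 CPM ± 14.3 at 1 h (SD, n = 3 each), a log2 fold change of -1.31 ± 0.26 (SE, adjusted p = 0.0491). That call was made in 10 of 22 alternatives, with an adjusted p from 0.000431 to 0.197, and in 2 of the 9 fits without a single library (without 0 h replicate 2 and without 1 h replicate 3).

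In total 94 of 15586 genes differed, 79 higher and 15 lower at 8 h, and 52 of those higher and 3 of those lower were also called in that direction at 8 h against 0 h. Further genes higher at 8 h were Hif3a by 1.95 ± 0.19 (SE), Cldn1, a tight junction protein, by 1.78 ± 0.35 (SE), Fkbp5 by 1.63 ± 0.19 (SE), Fam83d by 1.54 ± 0.14 (SE) and Sult1a1, a sulfotransferase, by 1.49 ± 0.25 (SE). Further genes lower at 8 h were Adamts1, a matrix protease, by a log2 fold change of -1.12 ± 0.16 (SE), Rab38, a trafficking GTPase, by -1.16 ± 0.20 (SE), Mmp14 by -0.88 ± 0.12 (SE), Slc7a11, a cystine transporter, by -0.61 ± 0.12 (SE) and Rgs16, a regulator of G protein signalling found in relay neurons, by -0.50 ± 0.08 (SE). Of 21 named genes called between 8 h and 1 h, 9 were called in all fits without a single library: Plin4, Cdkn1a, Zbtb16, Hif3a, Fkbp5, Cftr, Fam83d, Adamts1 and Mmp14. Cldn1 was called in 1 of 9, Tekt4 in 4, Ppp1r3g in 5, Slc7a11 in 2, Rab38 and Sult1a1 in 5, and Rgs16 in 7. Tnfsf12 did not pass, at -0.09 ± 0.20 (SE, adjusted p = 0.927).

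Of 24 glucocorticoid-induced genes, 13 were higher at 8 h than at 1 h, and 18 adjusted over the list alone. The list was higher as a group (camera, adjusted p = 2.13e-28), also with an estimated correlation (adjusted p = 0.0114). Of 33 rapid activity genes, 1 was lower, Npas4, also adjusted over the list alone, and the list was lower as a group (adjusted p = 0.00515, and adjusted p = 0.583 with an estimated correlation). It was not called without the libraries with the most Neurod6 (adjusted p = 0.0573). Of 33 potassium and HCN channel genes, 3 were higher, among them Kcnn3 and Kcnf1, and 4 adjusted over the list alone (camera, adjusted p = 0.00391, and adjusted p = 0.328 with an estimated correlation). Without the libraries with the most Neurod6, 0 of these channel genes were called higher, and 1 with Xist as a covariate. In total 10 of 32 lists were called, 5 higher and 5 lower, of which 1 was called with an estimated correlation and 1 with fry, the glucocorticoid-induced list in each case.

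Cell type lists were among these calls between 8 h and 1 h. Nuclear non-coding RNAs and ribosomal protein genes were not called (camera, adjusted p = 0.794 and 0.103). Inhibitory neuron markers (median 0.31, adjusted p = 0.00441), astrocyte markers (median 0.05, adjusted p = 0.0452) and nuclear-encoded respiratory chain genes (median 0.09, adjusted p = 0.000443) were higher. Sex-chromosome genes (median -0.38, adjusted p = 0.0447), sterol synthesis genes (median -0.13, adjusted p = 7.52e-05), interferon-stimulated genes (median -0.33, adjusted p = 0.00441) and ERK feedback genes (median -0.15, adjusted p = 0.0398) were lower. Each of these 7 had an adjusted p = 0.583 with an estimated correlation. Without the libraries with the most Neurod6, ERK feedback genes were not called (adjusted p = 0.194). None of their members passed over all genes, and 2 astrocyte markers, among 18, were higher adjusted over the list alone. The sex-chromosome call was lost with the replicate block (camera, adjusted p = 0.730). Y-linked RNA was nearly absent from 8 h replicate 2: Ddx3y stood at 38.5, 0.053 and 28.6 CPM in the 8 h replicates and at 35.1, 25.2 and 28.7 CPM at 1 h. The total count of 94 was 20 without 1 h replicate 1, 31 without 1 h replicate 3, and 38, 26 and 45 without 8 h replicates 1, 2 and 3. Without 8 h replicate 1 or 2, Tnfrsf12a was at an adjusted p of 0.0504 or 0.0652, with log2 fold changes of 0.92 and 0.91.

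Fosb and Fosl2, all of the genes called at 1 h, were called higher in both comparisons with 0 h. No gene was called lower in both. In the authors' deposited tables, 8 genes were higher in both at an FDR under 0.05, where independent lists would share 0.15. Of 81 genes that rose at 8 h, 64 were above 0 at 1 h, with a median log2 fold change there of 0.09. These 2 counts also rest on the shared controls. For the calls made here, lists that are independent would share 0.0107 genes. Simulated unchanged groups against the same controls shared 0.05 on average. Across 15586 genes, which are not independent replicates, the log2 fold changes at 1 h and 8 h had a correlation of 0.50, where the simulation gave 0.54 ± 0.01 (SD of 20 simulated data sets). Their covariance was 0.0313 against 0.0299 ± 0.0013 in the simulation, a difference of 0.0014. Shared controls alone thus gave as high a correlation in the simulation, so the correlation does not show a shared response. With 3 control libraries, the controls could not be split into parts of at least 2, so part of the shared calls may also come from the shared controls.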

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

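Tests of the difference between the responses at 8 h and 1 h, in the fit of all 9 libraries, set apart 24 of the genes that the naming rule took from the comparisons with 0 h. Fam83d, Cldn1, Sult1a1, Rab38, Slc7a11, B3galt2, Ndst3 and Npas4, which that rule took from the comparison of 8 h with 1 h alone, differed too, of which Ndst3 was called in 1 and B3galt2 in 4 of the 9 fits without a single library. Of 24 glucocorticoid-induced genes 12 rose at 8 h, and the list's call there was lost with an estimated correlation (adjusted p = 0.117). At 1 h the 8 members given here lay between -0.93 (Plin4) and 0.31 (Map3k6) on the log2 scale and none passed. The difference of 8 h minus 1 h, on the log2 scale, was 4.12 for Plin4, 2.45 for Cdkn1a, 1.92 for Zbtb16, 1.63 for Fkbp5, 1.55 for Map3k6, 0.90 for Sgk1, 0.89 for Mertk and 0.76 for Nfkbia. Other genes with a larger value at 8 h were Tekt4 (1.99), Hif3a (1.95), Cftr (1.65), Ppp1r3g (1.32), Car7 (1.296), Tnfrsf12a (0.97), Kcnf1 (0.82), Slc2a1 (0.55), Kcnn3 (0.50), Vgf (0.44) and Prkcd (0.34), of which Tekt4 was called in 4 and Ppp1r3g in 5 of those 9 fits. Lower at 8 h than at 1 h were Adamts1 (-1.12), Mmp14 (-0.88), Rgs16 (-0.50), Zfp804a (-0.49) and Sox2 (-0.33). Adamts1 stood at 0.78 at 1 h and -0.35 at 8 h, neither of which passed against 0 h.

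The rise of glucocorticoid-induced genes at 8 h was set against 3 technical explanations, and the tests of neighbouring tissue and of the sex make-up were chosen after their results were seen. Without 0 h replicate 2, which holds cortical and hippocampal transcripts, the median log2 fold change of all 24 measured members was 83.7% of its value with it (0.80 and 0.96), and the 12 that rose with it rose again, which argues against that library as the whole source. With Xist as a covariate, which ended 36 of the 90 calls, the median of the 24 members was 101.2% of its value without it (0.97 and 0.96). Of the 12 that rose, 11 rose again. The covariate was on the log2 scale, where 0 h replicate 3 (0.334 CPM) lies far below the other libraries (217 to 852 CPM). It therefore mainly sets that library apart and follows the female share of the others little. These values argue against the lack of Xist in 0 h replicate 3 as the whole source, and the sex make-up of the libraries stays open. The time of day at collection stays open: clock output genes minus Arntl, Npas2 and Clock shifted by 0.10 (log2) between 0 h and 8 h, with a 95% interval from -0.41 to 0.60 that is too wide to decide. Light itself, which the design names, cannot be told apart from the time of day for these genes, since 8 h of light also means a different hour of the day unless the start of light was moved.

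For each comparison, the 6 libraries can be split in 10 ways, which is too few for a share under 0.05. The count of 1 h against 0 h was 2, that of 8 h against 0 h was 90 and that of 8 h against 1 h was 94. In each case the highest count of the other splits was 0, so 1 split, the real one, reached the count.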

How the results depend on the processing

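The choice of test and single libraries moved the counts of calls more than the scaling did. At 1 h the count of 2 became 14 with DESeq2, 17 with the exact test, 1 with limma-voom, 1 with a mean of at least 1 CPM, and 0 with the Xist covariate. Leaving out each library gave 0 to 9. At 8 h the count of 90 became 270 with DESeq2, 269 with the exact test and 53 with a change of at least 1.5-fold, and 33 to 84 without single libraries. Between 8 h and 1 h the count of 94 became 200, 199 and 41 under these settings, and 20 to 127 without single libraries. Of the alternatives added after seeing the data, leaving out the libraries with cortical transcripts gave 0, 84 and 28 calls in the 3 comparisons, a covariate for those transcripts gave 151 at 8 h, and the other option of glmQLFit gave 1 at 1 h. Fewer libraries lower the power by construction, and the cause of the other shifts was not tested.

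The replicate numbers were checked for pairing, and the correlations of same-numbered libraries ran from -0.20 to 0.18. For 0 h with 8 h they were 0.033, 0.13 and 0.135, and for replicate 3 they were 0.164, 0.135 and 0.179. Those below 0 were -0.102 and -0.199 (0 h with 1 h, replicates 1 and 2) and -0.165 (1 h with 8 h, replicate 2). The highest of all, 0.24, was between 0 h replicate 2 and 1 h replicate 1. Pairing by number is therefore neither shown nor set aside. With the replicate block, the count was 0 at 1 h, 158 at 8 h and 75 between 8 h and 1 h. At 8 h all 90 genes of the main fit were called again with the block. Not every library correlated best with its own number.

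Of 12 lists called at 1 h, 0 were called with an estimated correlation and 0 with fry, and of 14 at 8 h, 0 and 2. Without single libraries the numbers were 11 to 17 and 10 to 15. The overlap of 2 genes became 0 at an adjusted p under 0.01 and 1 with a mean of at least 1 CPM, and it is 0 by construction wherever the count at 1 h is 0, as with the block, the Xist covariate, the fit without the libraries with cortical transcripts and 5 of 6 fits without a single library. No named gene reversed its direction among called values. Of 1368 alternative values of named genes at 8 h, 1269 kept their side of the threshold, as did 1125 of 1157 at 1 h and 403 of 484 between 8 h and 1 h. These shares include genes that were not called, and at 1 h 2 of 61 named genes were called. Of 19 alternatives at 1 h, Fosb was called in 8 and Fosl2 in 11.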

Other observations

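Receptor and matrix genes showed few changes. Of 30 glutamate receptor and scaffold genes, 1 rose at 8 h, and 2 adjusted over the list alone. This was Grik3, a kainate receptor subunit, by 0.46 ± 0.08 (log2 ± SE, adjusted p = 0.0362), which was called in 0 of the 6 fits without a single library (adjusted p up to 0.187). The list was at an adjusted p of 0.475 at both times, but was called higher without 0 h replicate 2 (adjusted p = 0.0124 at 1 h and 0.0189 at 8 h). GABA genes were at an adjusted p of 0.990 at 8 h and 0.907 at 1 h. In the list of known retinogeniculate refinement genes, Tnfrsf12a and Mertk rose at 8 h among 28 measured, and 3 rose and 1 fell adjusted over the list alone, while the list was not called (adjusted p = 0.728). Extracellular matrix genes had 1 fall, Tnc, among 28 at 8 h, with 2 rises and 2 falls adjusted over the list alone (adjusted p = 0.991).

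Among cell types, Fgfr3, a receptor of astrocytes, rose at 8 h by 0.36 ± 0.06 (log2 ± SE, adjusted p = 0.0273), as the 1 of 18 astrocyte markers to rise, over all genes and adjusted over the list alone. It was called in 0 of the 6 fits without a single library (adjusted p up to 0.187). Slc2a1, the glucose transporter of brain endothelium, rose by 0.64 ± 0.09 (adjusted p = 0.00927), as the 1 of 16 endothelial markers. Adjusted over the list alone, 2 endothelial markers rose and 1 fell. Relay neuron markers were called higher at 1 h (adjusted p = 0.0287, and adjusted p = 0.554 with an estimated correlation), but in 2 of the 6 fits without a single library: not without 0 h replicates 1 or 2 (adjusted p = 0.111 and 0.0964) or 1 h replicates 2 or 3 (adjusted p = 0.134 and 0.642). They were not called at 8 h (adjusted p = 0.0530). Inhibitory neuron markers were not called at 1 h (adjusted p = 0.475), but were lower without 0 h replicate 2 (adjusted p = 1.68e-11), the library with the least Gad2. Mitochondrially encoded genes, called higher at 8 h (adjusted p = 0.0377, and adjusted p = 0.712 with an estimated correlation), did not pass without that library, with the opposite sign (adjusted p = 0.485), and nuclear-encoded respiratory chain genes, called higher at 8 h (adjusted p = 0.0262, and adjusted p = 0.814 with an estimated correlation), were at 0.906 without it. Both calls were made in 2 of the 6 fits without a single library. The mitochondrial list was also lost without 0 h replicate 1 (adjusted p = 0.0958) or 8 h replicates 1 or 2 (0.144 and 0.0674), and the respiratory chain list without 0 h replicate 1 (0.0771) or 8 h replicates 1 or 3 (0.3005 and 0.113). Heat shock genes were called higher at 8 h (adjusted p = 0.00708, and adjusted p = 0.659 with an estimated correlation) but not without 0 h replicate 2 (adjusted p = 0.166), 8 h replicate 1 (adjusted p = 0.0606) or 8 h replicate 2 (adjusted p = 0.102). At 8 h inhibitory neuron markers changed direction with the 0 h library left out, lower without replicate 2 (adjusted p = 0.0082) and higher without replicate 3 (adjusted p = 0.000108).

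The tests of the 2 patterns below, on Xist with Y-linked RNA and on cortical and hippocampal genes, were chosen after the results were seen. No biological explanation from the design was tested for them. Xist and Y-linked RNA were found in the same library in 7 of 9 cases. With tissue of both sexes in a library, its Xist level relative to 8 h replicate 2 and its Y-linked level relative to 0 h replicate 3 should add up to about 1. The sums lay between 0.967 and 1.08 in the 7 libraries, and all 7 met the limits set (0.7 to 1.3), so the hypothesis that fits these sums is that tissue of male and female mice entered these libraries. That puts in doubt that the 3 libraries of a group are 3 separate mice, as the labels count them, and every SD, SE and p given here treats them as independent. Reads spilling over between libraries are argued against, since Xist in 0 h replicate 3 was 0.071% of the mean of the others.

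Cortical and hippocampal genes in 0 h replicate 2 and 1 h replicate 1 may come from neighbouring tissue taken with the dLGN. Over 40 genes of lists written after Neurod6 was seen, 31 of which the other 7 libraries also express at 1 CPM or more, the lower median log2 ratio to those libraries was 0.64, between the limits set for and against, and 65.0% were above 0 in both. The 14 genes shared by cortex and hippocampus were all above 0 in both, with medians of 2.13 and 1.93, while the cortical genes alone had medians of -0.02 and 0.04, so neighbouring tissue stays open. Among members chosen after their values were seen, Camk2a stood at 1292 CPM in 0 h replicate 2 against 965 in the others, Mef2c at 176 against 174 and Neurod2 at 16.6 against 1.52 CPM. The median of hippocampal genes exceeded that of cortical genes by 0.70 and 1.05, but 3 of 13 cortical genes (Tbr1, Fezf2 and Lamp5) had ratios above 1 in both, and others, such as Mef2c, have a level in the other libraries that would hide a small share, so cortex is not set aside.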
